A study of Populus cathayana with 4 samples.

How the data were processed

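Leaf RNA from the fourth fully expanded leaves of Populus cathayana was measured in 4 libraries, 1 for each combination of sex and UV-B level after 100 days. Each library pooled RNA from 9 plants in equal shares, per the labels' protocols. The same protocols mention 3 biological replicates of the RNA extraction, but the labels list 1 library per group. Libraries were made from oligo-dT cDNA cut with NlaIII and MmeI, which leaves one 17 bp tag per transcript, and were sequenced on separate flow cell lanes, per the labels' protocols. Lane and group can therefore not be told apart.

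The deposited table gives raw tag counts per gene for each library, with the library total printed in each column header, per the file headers. It also gives values headed TPM. These deposited values are CPM, that is, tags scaled by the header total without a length correction: recomputing them from the raw counts gave 100% of them within 0.005. How the authors assigned tags to genes, how many mismatches they allowed and which genome build they used are not given in the sources used here, so no coordinates are printed. The rows carry Potri gene identifiers and, for part of them, a best database hit and gene ontology terms, per the file headers. Gene descriptions in the text are those of the best hit. Of 19100 rows, from 18465 loci, 2940 had a description that names a protein, and of the 10741 tested rows 1693 did (15.8%). No count of 1 occurs in the table, and 2158 to 2825 rows per library have a count of 2, so that a listed 0 can stand for 0 or 1 tag. The listed rows hold a part of each library, and so the header totals, not the sums of the listed rows, were used as library totals.

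Only the raw counts were analysed. The CPM columns were used for the unit check and were recomputed for the plots. Groups were taken from the labels. Rows with fewer than 10 counts over the 4 libraries were left out, and 10741 remained. With 1 library per group no replicate spread can be estimated. Each comparison of a pair of libraries therefore used an exact two-sided conditional binomial test of the gene's counts given the library totals, adjusted by Benjamini-Hochberg over the 10741 genes. A gene was called where the adjusted p was below 0.001 and the ratio of CPM was at least 2-fold. The difference between the sexes in their response used an exact conditional test of the gene's 4 counts, with the noncentral hypergeometric distribution set by the 4 library totals, and the same thresholds. Both tests compare libraries and cover counting error only, as do the intervals. They treat each tag as an independent count, although the tags were copied by PCR, per the labels' protocols. Intervals are exact 95% conditional intervals of the ratio of counts, or of the ratio of ratios. A gene at 0 counts in 1 library is given as a bound against 3 counts there.

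The tests, thresholds, lists and named-gene rule were chosen before the data were examined. The rule named genes with an informative description and at least 50 counts in the higher library. For each comparison of a pair of libraries it took the 5 largest and 5 smallest log2 ratios among called genes, and from every list up to 2 called members per direction. For the test between the sexes it took the 5 largest and 5 smallest ratios of ratios. A few genes outside the rule are named where they are the most abundant member of a list, one of its few calls or part of a pattern, and these were chosen after their values were seen. They are pectinesterase, COP1-like, DnaJ, pheophorbide A oxygenase, dehydrin, MADS-box and fasciclin genes, the beta-fructofuranosidase, and those named so in the closing text.

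The 36 gene lists are word patterns on the descriptions. For the 21 lists with at least 5 tested members, the median log2 ratio with 0.5 added to each count was set among 10000 random lists of the same size, matched in 20 bins of mean CPM. The percentile describes these libraries and is not a p-value. Calls in a list are given over all genes tested and adjusted over the list alone. Gene ontology terms with 20 to 500 tested members, 196 in all, were treated in the same way, a step added after the data were seen. Some lists hold members that their name does not cover: 6 potassium channels in the jasmonate list, 2 methylenetetrahydrofolate reductases in the ethylene list, and plastid or mitochondrial proteins in the ribosome list. The primary cell wall pattern takes any cellulose synthase or arabinogalactan protein, whichever wall it serves. The pattern for glutathione S-transferases missed the wording glutathione transferase.

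Each test was run first on simulated counts drawn from the real means and totals of the 10741 genes, with 100 genes changed 3-fold and 100 changed 8-fold. For UV-B in males 19.0% of the 3-fold and 65.0% of the 8-fold changes were recovered, and 94.4% and 100% among those expected to have at least 50 counts in the higher library. For UV-B in females the figures were 24.0% and 65.0% (83.3% and 100% among the deeper genes), and for sex under reduced UV-B 29.0% and 68.0% (81.3% and 100%). For sex under ambient UV-B they were 27.0% and 48.0% (89.3% and 97.6%), and for the test between the sexes 15.0% and 34.0% (48.4% and 82.9%). No simulated unchanged gene was called, and no call had the wrong direction. The simulated counts had no spread between pools, which is what the tests assume. These figures therefore cover counting error only and do not give the rate of false calls between real pools. The list percentile was tried for UV-B in males only. Of 100 random lists of 30 genes, 7.00% fell outside the central 95%, and 100% of lists shifted 2-fold did.

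The alternatives were scaling by edgeR TMM factors or DESeq2 size factors, no low-count filter, at least 100 counts over the 4 libraries, an adjusted p threshold of 0.05, and an edgeR exact test with an assumed biological coefficient of variation of 0.1 or 0.3. An alternative pseudocount, planned in case the file held no counts, does not apply because it holds counts. Alternatives added after seeing the data were the sum of the listed rows as library total, UV-B calls without the genes whose best hit is plastid-encoded, and lists without mismatched and plastid-encoded members. A best hit was taken as plastid-encoded where it is an organelle reference record or is marked as chloroplast, excluding mitochondrial hits. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers. For the same reason no other split of the libraries was counted. Correlations between comparisons were set beside the values from 100 sets of simulated unchanged libraries. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.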

Results

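Leaf transcripts were counted in Populus cathayana, a poplar with separate male and female trees, by 3′ tag sequencing, in which a transcript is counted through a 17 bp tag next to a restriction site. Cuttings of each sex had grown for 100 days under ambient solar UV-B or under reduced solar UV-B. This gave 4 groups: males under reduced UV-B, males under ambient UV-B, females under reduced UV-B and females under ambient UV-B. Each group had 1 library, made from the pooled RNA of 9 plants, so no value has a replicate error.

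The 19100 entries of the count table, called genes here, held 636702 tags in males under reduced UV-B, 722533 in males under ambient UV-B, 660483 in females under reduced UV-B and 624926 in females under ambient UV-B. These are only part of the sequenced tags. Their share of the library total was 14.9% (exact binomial 95% interval 14.8% to 14.9%) in males under reduced UV-B and 17.2% (17.1% to 17.2%) in males under ambient UV-B. It was 15.0% (15.0% to 15.1%) in females under reduced UV-B and 14.4% (14.4% to 14.5%) in females under ambient UV-B. Males under ambient UV-B also had the most genes at 0 counts, 7001 against 5431 to 5948 in the other libraries. The most abundant gene, Potri.005G190100.1, held 2.10% to 5.97% of the listed counts. Of the 19100 genes, 10741 had at least 10 counts over the 4 libraries and were tested, and 1693 of these had an informative description.

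Across the 3478 genes with at least 100 counts, libraries of the same sex were the most alike. Pearson's r between log2 values was 0.88 between the male libraries and 0.87 between the female libraries, against 0.63 to 0.67 across the sexes. These correlations are across genes, which are not replicates.

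A gene was called when an exact test on its counts had an adjusted p below 0.001 and its CPM, the counts scaled by the library total, differed at least 2-fold. The test compares libraries and covers counting error only, so a call says that 2 pooled libraries differed, without a replicate check on the condition. Log2 ratios carry exact 95% counting intervals where these are given.

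**Figure D1:**
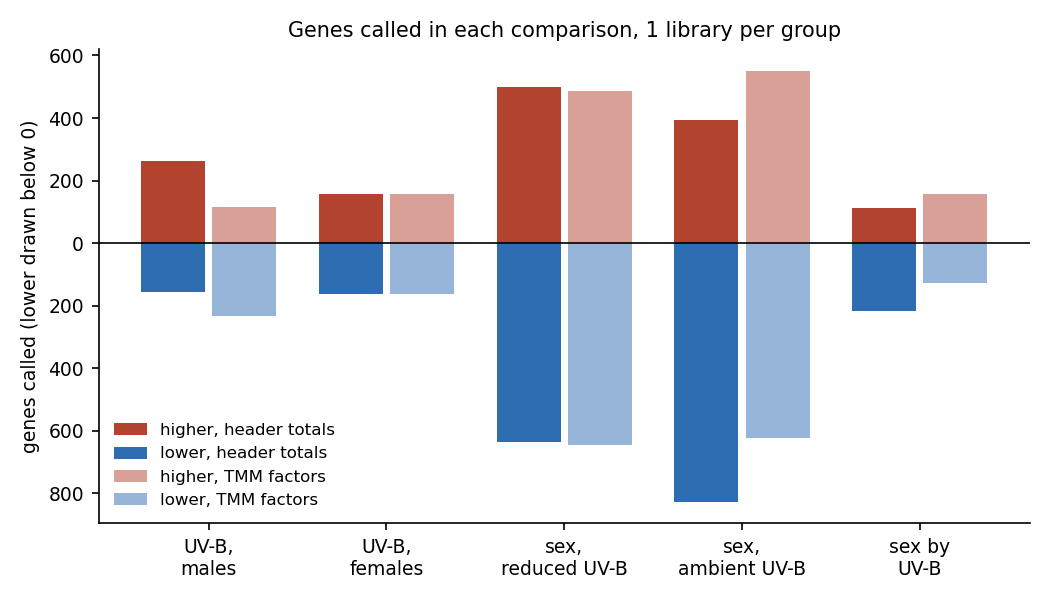
Number of genes called higher (above 0) and lower (below 0) in each comparison, scaled by library totals (dark bars) or by TMM factors (light bars), with 1 library per group. Sex comparisons gave 1134 and 1219 calls and UV-B comparisons 421 and 320 with library totals, and the balance of directions in males moved with the scaling.

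The first comparison asked what ambient UV-B changed in male leaves. Under ambient UV-B, males had more transcript of the defence proteins polyphenol oxidase and a Kunitz-type trypsin inhibitor, of metallothionein 3a, of a glutaredoxin and of some AP2/ERF transcription factors. Glutathione transferase GSTU20, a xyloglucan endotransglycosylase, a lignin methyltransferase and a group of genes resembling plastid-encoded genes fell. Cell wall lists were low as groups. In all, 264 genes were called higher and 157 lower, of which 12 and 23 differed more than 8-fold. With TMM factors the median of all genes moved by -0.21 on the log2 scale and the split became 117 higher and 232 lower. DESeq2 size factors gave 125 and 225. Each male log2 ratio below, given with library totals, is 0.21 lower with TMM factors, and genes whose call ended are named. With an assumed coefficient of variation of 0.3 between pools, 0 higher and 5 lower calls were left, and 1 of the 30 genes named by rule, GSTU20.

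Among the genes that rose in males, polyphenol oxidase (Potri.011G108300.1), which oxidises phenolics in wounded leaves, went from 13 to 126 counts, a log2 ratio of 3.30 (interval 2.48 to 4.25). The Kunitz-type trypsin inhibitor Potri.019G124400.2, of a family that blocks insect digestive proteases, went from 372 to 2014 counts (2.46, interval 2.30 to 2.63). Metallothionein 3a (Potri.011G118900.1), a small cysteine-rich metal-binding protein, went from 486 to 2104 counts (2.14, interval 2.00 to 2.28). The AP2/ERF transcription factor genes Potri.006G218200.1 and Potri.001G079800.1 rose by 3.18 and 1.88. A glycosyltransferase of family GT8 (Potri.008G192600.1) rose by 2.15. The glutaredoxin Potri.010G021800.1, a thiol oxidoreductase, rose by 1.90, and a TIP subfamily aquaporin (Potri.016G098200.1), a channel of the vacuole membrane, rose by 1.52. Calls for 6 further genes ended with TMM factors and with size factors. These were chalcone synthase Potri.001G051600.1 (1.08, from 50 to 104 counts), the Kunitz-type inhibitor KPI-C1 Potri.019G124600.1 (1.14), photosystem I apoprotein A1 Potri.002G211800.1 (1.03), ribosomal protein S3 Potri.002G206800.1 (1.03), SAUR gene Potri.019G002200.1 (1.01) and phosphate transporter Potri.008G186600.1 (1.36).

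Among the genes that fell in males, GSTU20 (Potri.008G175000.1), a tau class glutathione transferase that conjugates glutathione to reactive compounds, went from 131 to 3 counts, a log2 ratio of -5.42 (interval -7.72 to -3.84). An RNA-dependent RNA polymerase (Potri.006G253500.1), an enzyme class of gene silencing, went from 85 to 7 counts (-3.58, interval -4.93 to -2.47). XTH-6 (Potri.006G071200.1), a xyloglucan endotransglycosylase that loosens and rejoins primary walls, went from 138 to 17 counts (log2 interval -3.82 to -2.26). Caffeoyl-CoA O-methyltransferase (Potri.001G304800.1), a step in lignin monomer synthesis, went from 150 to 34 counts (-2.12, interval -2.70 to -1.57). A class III peroxidase (Potri.016G125000.1) had a log2 ratio of -2.76, SAUR gene Potri.004G165300.1 -1.72, thioredoxin h (Potri.017G076700.1) -1.17 and the transcription factor bHLH71 (Potri.003G093200.1) -1.56. The NAC factors Potri.019G031400.1 and Potri.017G063300.1 had log2 ratios of -1.59 and -1.22. A gene described as 1-aminocyclopropane-1-carboxylate, the ethylene precursor, had -1.12 (Potri.002G224100.1). Methylenetetrahydrofolate reductase (Potri.007G147300.1), which the ethylene list took in by its word pattern alone, had -1.56.

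Several genes that fell resemble genes of the plastid genome. They include ribosomal protein S3 Potri.012G047500.1, from 1446 to 197 counts (-2.85), a Ycf1-like gene Potri.011G073900.1 (-2.86), ribosomal protein S7 Potri.013G138900.1 (-1.98) and ATP synthase CF0 subunit C Potri.005G154900.1 (-1.59). Of 41 tested genes whose best database hit is plastid-encoded, 11 were called lower in males and 0 higher, against 0 and 0 in females. Their median log2 ratio was -0.76 in males (percentile 0.00 of matched lists) and -0.19 in females (percentile 2.19), so that both lay below the central 95%. The count of 0 higher depends on how such hits were taken, by organelle reference record or chloroplast mark. It leaves out photosystem I apoprotein A1 Potri.002G211800.1 and ribosomal protein S3 Potri.002G206800.1, described like members of the group, which were called higher in males until TMM factors were used. With TMM factors 15 were lower in males. The test between the sexes called 9 of them, each with the lower UV-B ratio in males. These genes held 4.08% of the listed counts in males under reduced UV-B (exact binomial 95% interval 4.03% to 4.13%) and 2.57% (2.53% to 2.61%) under ambient UV-B. In females the shares were 3.11% (3.07% to 3.15%) and 2.84% (2.79% to 2.88%).

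By fixed lists, the primary cell wall list had the lowest place in males. Its 12 members had a median log2 ratio of -1.23, at percentile 0.01 of 10000 matched random lists, and -0.88 with 0 counts set at 3. Over all genes tested 0 members were called higher and 1 lower, and adjusted over the list alone 0 and 3. Its most abundant member, pectinesterase Potri.014G149700.1, had 9582 and 15347 counts and a ratio of 0.71, opposite to the list, without a call. The secondary wall list, mostly laccases, which polymerise lignin, had a median of -0.89 (percentile 0.52), with 0 higher and 1 lower, and adjusted over the list alone 0 and 2. The 5 phenylpropanoid entry genes had a median of -1.37 (percentile 2.03), or -0.39 with 0 counts at 3, with no calls by either adjustment. Their most abundant member, phenylalanine ammonia-lyase Potri.016G091100.1, stayed at 468 and 515 counts.

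The photosystem and antenna list of 28 genes had a median of -0.23 in males (percentile 0.23), with 1 called higher and 1 lower by either adjustment. Without its 9 members with a plastid-encoded best hit, as defined above, the median was 0.04 (percentile 14.9), a change of sign. The 19 left still held photosystem I apoprotein A1 Potri.002G211800.1, described like genes taken out. Among members with at least 100 counts the median was also 0.04, at percentile 6.92. Likewise the list named cytosolic ribosome had a median of -0.16 (percentile 1.29), with 1 higher and 3 lower by either adjustment. Without 11 members, mismatched or with such a hit, it was 0.51 (percentile 80.5), and the 7 left still held ribosomal protein S3 Potri.002G206800.1. Ethylene-related genes, mainly AP2/ERF factors, had 6 members higher and 2 lower of 67 by either adjustment, with a median inside the central 95% of matched lists. Defence proteins had 3 higher and 1 lower of 29 by either adjustment, but 1 higher and 2 lower with TMM factors and with size factors. Their median was inside the central 95%, and in the 9 members with at least 100 counts it was -0.32 (percentile 0.25). The 16 flavonoid genes had a median of 0.37 and a mean of -0.03, with chalcone synthase as the single call by either adjustment. The 16 proteasome and ubiquitin genes likewise had a median of 0.36 and a mean of -0.05, with 0 calls over all genes tested, and 1 higher and 1 lower adjusted over the list alone. Among its members with at least 100 counts the median was 0.76 (percentile 98.4). The cell division list had 0 calls by either adjustment.

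The second comparison asked the same of female leaves. Females under ambient UV-B had more transcript of a different Kunitz-type inhibitor, of GSTU20, of glutaredoxins and of metallothionein 3a. A cytochrome P450, an aminotransferase, cellulose synthases, a NAC factor, a 2-cys peroxiredoxin and light-harvesting genes fell. Cell wall, wax and photosystem lists were low as groups, and the thioredoxin and glutaredoxin list was high. There were 157 genes called higher and 163 lower, of which 23 and 25 differed more than 8-fold. TMM factors gave 156 and 164. With an assumed coefficient of variation of 0.3, 3 higher and 11 lower calls were left, and 1 of the 22 genes named by rule, cytochrome P450 Potri.014G037900.1.

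Among the genes that rose in females, the Kunitz-type trypsin inhibitor Potri.001G309900.1 went from 2 to 53 counts, a log2 ratio of 4.75 (interval 2.83 to 7.83). Cytochrome P450 Potri.001G270600.1, of a large family of oxidising enzymes, went from 11 to 106 counts (3.29, interval 2.39 to 4.34). A stress-induced hydrophobic peptide (Potri.005G002100.1) went from 11 to 93 counts (3.10, interval 2.20 to 4.15). GSTU20 went from 21 to 155 counts (2.91, interval 2.24 to 3.64), opposite to its fall in males. The glutaredoxin Potri.010G021800.1 rose by 2.38, and a second one, Potri.014G134200.1, by 1.03. Metallothionein 3a went from 1173 to 4457 counts (1.95, interval 1.86 to 2.04), which made it more abundant than in any other library. A multidrug resistance ABC transporter (Potri.003G034700.1) rose by 1.63 and a ubiquitin extension protein (Potri.002G190000.1) by 1.42. A disease resistance protein (Potri.012G074700.1) rose by 1.11 and a high affinity phosphate transporter (Potri.005G256100.1) by 1.05.

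Among the genes that fell in females, cytochrome P450 Potri.014G037900.1 went from 171 to 5 counts, a log2 ratio of -5.07 (interval -6.71 to -3.82), while males had 647 and 628 counts. An aminotransferase (Potri.017G014100.1) went from 51 to 2 counts (-4.65, interval -7.73 to -2.72). Cellulose synthase genes Potri.002G257900.1, from 63 to 5 counts, and Potri.002G066600.1, from 93 to 25 counts, had log2 ratios of -3.63 and -1.87. A NAC factor (Potri.011G153300.1) had -2.61, ribosomal protein S9 (Potri.012G144700.1) -2.07 and caffeoyl-CoA O-methyltransferase -1.87. The Kunitz-type inhibitor that rose in males, Potri.019G124400.2, had -1.53. The 2-cys peroxiredoxin Potri.016G072100.1, which reduces peroxides in the chloroplast, went from 215 to 78 counts (-1.44). The antenna genes Lhcb2 (Potri.014G165100.1) and Lhcb1 (Potri.005G239200.2), which bind chlorophyll in photosystem II, also fell, with a log2 ratio of -1.06 for Lhcb2, and the Lhcb1 call ended with size factors.

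Of the fixed lists, the primary cell wall list again had the lowest place. Its median was -1.32 (percentile 0.00 of the matched lists, that is, below them all to the precision given), and -1.20 with 0 counts at 3. It had 0 members higher and 4 lower by either adjustment, 2 cellulose synthases, XTH-6 and a fasciclin-like arabinogalactan protein. The last is also in the secondary wall list, which shares 3 members with this list, so the list is not limited to primary walls. Pectinesterase Potri.014G149700.1 had 15133 and 8872 counts, without a call. The secondary wall list had a median of -1.56 (percentile 0.07), with 0 higher and 1 lower by either adjustment. The 7 wax genes, all ketoacyl-CoA synthases, which elongate wax lipids, had a median of -1.20 (percentile 1.46) and 0 calls by either adjustment. With 0 counts at 3 it was -0.98. In males the wax median was -0.93, inside the central 95%.

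The photosystem and antenna median in females was -0.47 (percentile 0.15), with 0 higher and 2 lower by either adjustment. It stayed outside the central 95% without the members with a plastid-encoded best hit. The 30 thioredoxin and glutaredoxin genes had a median of 0.36 (percentile 99.0), with 2 higher and 0 lower by either adjustment. Among its 15 members with at least 100 counts the median was 0.23, inside the central 95%. Defence proteins had 4 higher and 1 lower by either adjustment. The ethylene list, with 6 members higher in males, had 0 calls in females by either adjustment, and the test between the sexes called 3 of its members lower. That became 1 lower with TMM factors, and 1 higher and 1 lower with size factors. Phenylpropanoid entry genes had a median of -0.45 and a mean of 0.40, without a call. Medians and means also differed in sign for the auxin, gibberellin, cell division, transport and NAC lists, with at most 2 members called in either direction.

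**Figure D2:**
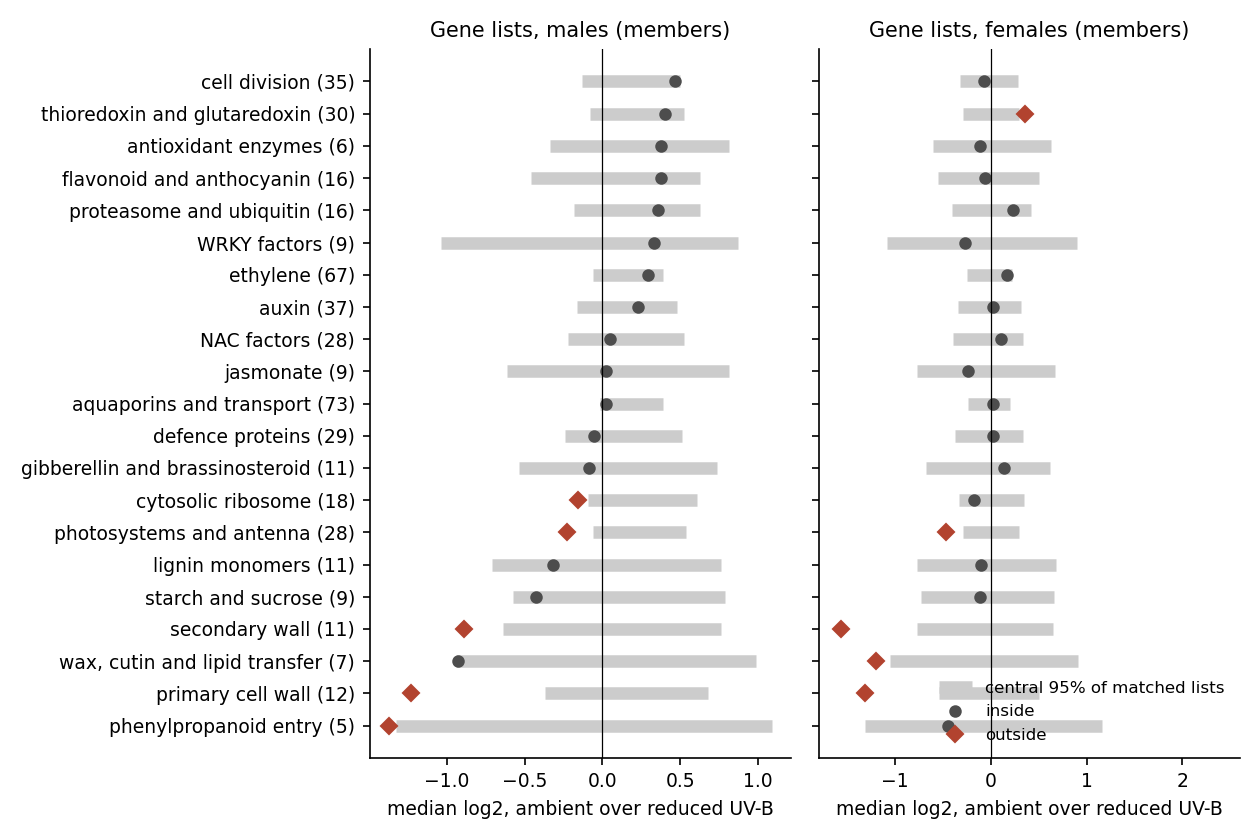
Median log2 ratio of ambient over reduced UV-B for each fixed gene list in males (left) and females (right), with grey bars for the central 95% of 10000 matched random lists and the number of members in brackets. The primary cell wall list lies at -1.23 and -1.32, and red diamonds mark lists outside the bar.

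Few UV-B calls were shared between the sexes, and the log2 ratios of the sexes were weakly correlated across genes. Each ratio compares pools without replicates, and spread between pools, which was not measured, can lower both the sharing and the correlation. Low sharing therefore cannot show that the sexes respond differently. Of the genes called, 15 were higher in both sexes, where independent lists would share 3.86, and 19 were lower in both, against 2.38. That expectation treats all tested genes as equally likely to be called. It is too low, since 339 of 421 male and 258 of 320 female calls lay among the 3478 genes with at least 100 counts. With TMM factors these counts were 11 and 27. Across the 3478 genes with at least 100 counts, the UV-B log2 ratios of the sexes had r = 0.18 and rho = 0.16, with a covariance of 0.11 against 0.00034 in simulated unchanged libraries. Only 4 of the shared genes had an informative description. The glutaredoxin Potri.010G021800.1 and metallothionein 3a rose in both, and XTH-6 and caffeoyl-CoA O-methyltransferase fell in both. A further 9 genes were called in opposite directions. Of these, 5 were higher in males and lower in females, against 4.01 for independent lists, and 4 the other way, against 2.29. Those counts are near the expectation, which is again too low.

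**Figure D3:**
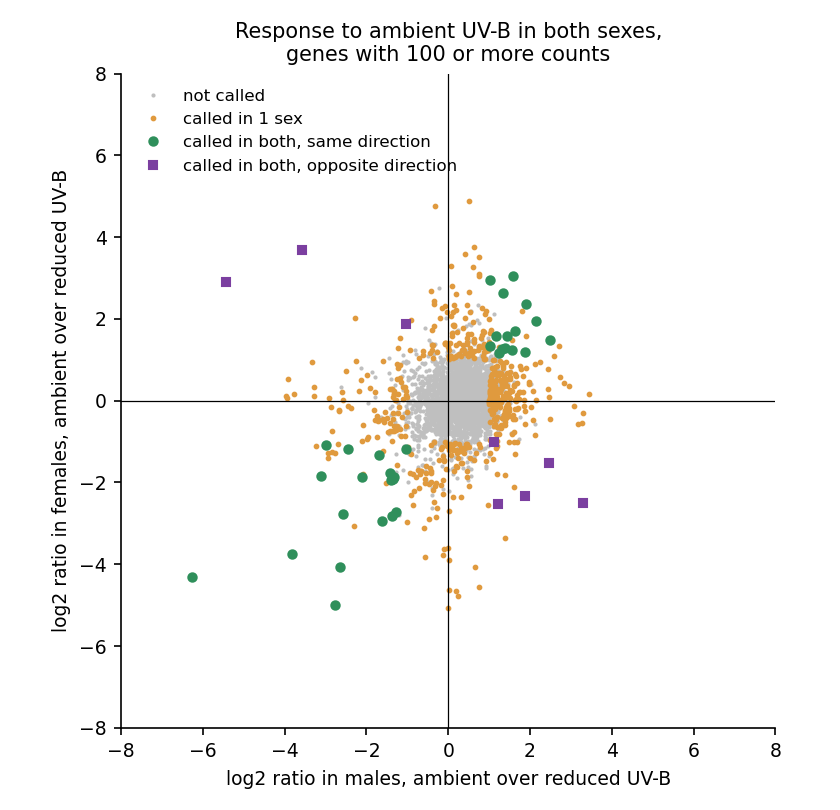
Log2 ratio of ambient over reduced UV-B in females against that in males, one point per gene with at least 100 counts over the 4 libraries. Genes called in both sexes in the same direction are green and in opposite directions purple, and the correlation across genes is r = 0.18.

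The third comparison asked where the UV-B ratios of the female and male libraries differed, by setting the female ratio against the male one in a single test on the 4 counts. The female ratio was called higher for 111 genes and lower for 217. TMM factors moved the median of all genes by 0.20 and turned the split into 157 higher and 126 lower. Of the 10 genes named by rule, all kept their calls with TMM factors and with size factors. A spread between pools was not tried for this test.

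GSTU20 had the highest ratio of ratios, 8.08 on the log2 scale (interval 6.51 to 10.69), since it fell in males and rose in females. The RNA-dependent RNA polymerase had 6.97 (interval 5.07 to 9.79), with 85 and 7 counts in males and 3 and 38 in females. Another glutathione transferase, EF1Bgamma2 (Potri.004G226300.1), part of the translation elongation complex, went from 48 to 0 counts in males and from 71 to 76 in females, so that its ratio was at least 17.1-fold higher in females. The Kunitz-type inhibitor Potri.001G309900.1 had 4.76 and cytochrome P450 Potri.001G270600.1 had 3.18. At the other end, polyphenol oxidase had -5.65 (interval -7.71 to -4.09), with 29 and 5 counts in females. Cytochrome P450 Potri.014G037900.1 had -4.92, the aminotransferase -4.52, the Kunitz-type inhibitor Potri.019G124400.2 -3.97 and cellulose synthase Potri.002G257900.1 -3.39. No fixed list had a median outside the central 95% in this test. Among members with at least 100 counts, defence proteins (0.35, percentile 98.3) and the ribosome list (0.15, percentile 97.9) lay above it. The primary cell wall list had a median of 0.05, and -0.93 at percentile 3.52, a change of sign, in the 7 members with at least 100 counts. It had 1 member higher, XTH-6, and 2 lower, cellulose synthase and pectinesterase Potri.014G149700.1, by either adjustment. The secondary wall, starch, thioredoxin, flavonoid and proteasome lists had medians and means of opposite sign there. Antioxidant enzymes had 2 lower by either adjustment, the 2-cys peroxiredoxin and glutathione reductase (Potri.015G037800.1).

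**Figure D4:**
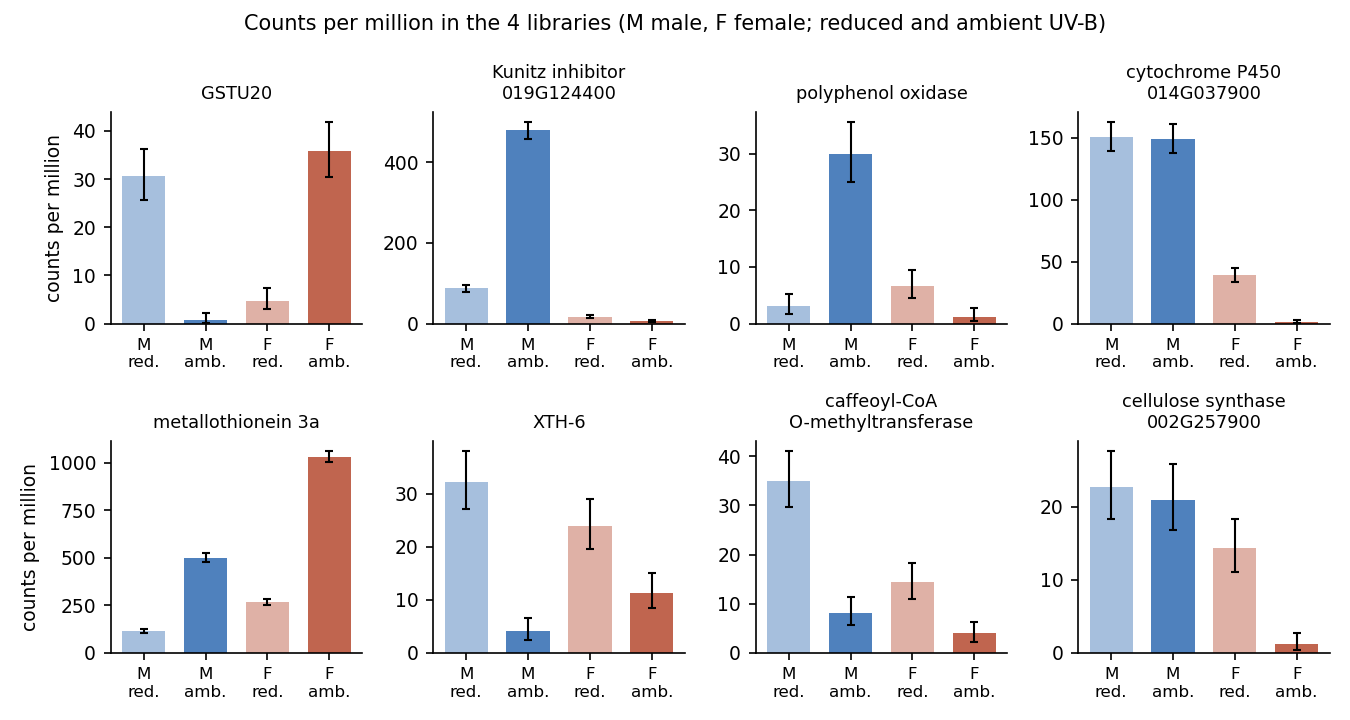
CPM in the 4 libraries for 8 genes, with bars starting at 0 and exact Poisson 95% intervals that cover counting error only. GSTU20 falls from 30.6 to 0.713 in males and rises from 4.78 to 35.8 in females, whereas metallothionein 3a rises in both sexes.

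The fourth comparison asked how females differed from males under reduced UV-B. Females had more transcript of an ammonium and a nitrate transporter, of plastocyanin and of alpha-amylase. They had less of several defence proteins and ethylene-related genes, of allene oxide synthase, and of 2 named chalcone synthases. As a group, the photosystem and antenna list had 3 members higher and 2 lower by either adjustment and a median of -0.06, inside the central 95%. There were 500 genes called higher in females and 634 lower, of which 66 and 141 differed more than 8-fold. TMM factors gave 485 and 644. The 44 genes named by rule all kept their calls with both scalings, but 12 did so with an assumed coefficient of variation of 0.3 between pools.

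Among genes higher in females, the ammonium transporter Potri.008G173800.1 had 560 counts against 75 in males, a log2 ratio of 2.86 (interval 2.51 to 3.23). The nitrate transporter Potri.014G157400.1 had 2.44, and a type-a response regulator of cytokinin signalling (Potri.008G193000.1) had 2.75. A ubiquitin extension protein (Potri.001G025300.1) had 81 counts against 3 (4.72, interval 3.12 to 7.03) and an nbs-lrr resistance protein (Potri.018G013500.1) 64 against 3 (4.38, interval 2.77 to 6.69). A lectin receptor kinase (Potri.002G086500.1) had 52 against 0, at least 16.9-fold higher. Plastocyanin (Potri.005G246100.1), which carries electrons to photosystem I, had 3017 counts against 1202 (1.29, interval 1.19 to 1.39). The antenna gene Lhcb4 (Potri.006G099500.1) had 1.07, magnesium-protoporphyrin O-methyltransferase of chlorophyll synthesis (Potri.012G106600.2) 1.35 and glutathione reductase 1.23. Alpha-amylase (Potri.017G093200.1), which breaks down starch, had 1.38, and metallothionein 3a 1.23. Histone genes Potri.007G013300.1 and Potri.009G028000.1 had 1.21 and 1.04.

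Among genes lower in females, the Kunitz-type inhibitor Potri.001G309900.1 had 2 counts against 207, a log2 ratio of -6.73 (interval -9.79 to -4.86). Cytochrome P450 Potri.007G084400.1 had 2 against 83 (-5.41, interval -8.48 to -3.51). A reductase of the lignan branch, phenylcoumaran benzylic ether reductase-like protein (Potri.007G123700.1), had 6 against 178 (-4.93, interval -6.39 to -3.78). SAUR gene Potri.004G165300.1 had -4.87 and the RNA-dependent RNA polymerase -4.86. Of other defence and hormone genes, thaumatin (Potri.001G102400.1) had 92 counts against 716 (log2 interval -3.33 to -2.68), and allene oxide synthase (Potri.002G130700.1), an entry step to jasmonate, had -2.05. The class III peroxidase had -4.41, the 1-aminocyclopropane-1-carboxylate gene -4.39, an auxin influx carrier (Potri.005G174000.1) -4.12, NAC factor Potri.017G063300.1 -4.09 and WRKY18 (Potri.003G169100.1) -2.10. The phosphate transporter Potri.002G005500.1 had -4.40. Chalcone synthases Potri.001G051500.1 and Potri.003G176800.1, the first step to flavonoids, had -1.98 and -1.77.

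By fixed lists, ethylene-related genes had a median of -0.52 (percentile 0.17), with 3 higher and 10 lower, and adjusted over the list alone 3 and 11. Flavonoid genes had a median of -0.83 (percentile 2.01) and -1.14 with 0 counts at 3, with 1 higher and 4 lower, and adjusted over the list alone 2 and 5. Defence proteins had 1 higher and 9 lower of 29 by either adjustment, with a median inside the central 95%. In their 9 members with at least 100 counts the median was -2.31, outside it. Starch and sucrose genes had a median of 1.10 (percentile 99.1), with 2 higher and 0 lower by either adjustment, alpha-amylase and a beta-fructofuranosidase. Proteasome and ubiquitin genes had a median of 0.61 (percentile 97.8), with 4 higher and 0 lower, and adjusted over the list alone 5 and 0. Among its members with at least 100 counts the percentile was 95.9, inside the central 95%. Ribosome genes had a median of -0.62 (percentile 1.26), or -0.18 inside the central 95% without plastid and mismatched members, with 0 higher and 1 lower by either adjustment. Among members with at least 100 counts its percentile was 2.88, also inside. Transport genes had 2 higher and 7 lower of 73, and adjusted over the list alone 2 and 8, with a median of 0.33 and a mean of -0.08. Medians and means also differed in sign for the wax and WRKY lists, without outlying medians.

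The fifth comparison asked how females differed from males under ambient UV-B. As under reduced UV-B, a nitrate transporter was higher in females, and several defence proteins, 2 chalcone synthases and allene oxide synthase were lower. GSTU20, EF1Bgamma2 and a further glutaredoxin stood higher in females here. Auxin and secondary wall lists stood lower. There were 393 genes called higher in females and 826 lower, of which 92 and 177 differed more than 8-fold. TMM factors moved the median of all genes by 0.19 and turned the split into 551 higher and 624 lower, so that each log2 ratio below is 0.19 higher with those factors. With an assumed coefficient of variation of 0.3 calls held for 17 of 38 genes named by rule. They held with both scalings for 37, and ended for SAUR gene Potri.012G023400.1 (-1.11).

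Among genes higher in females, GSTU20 had 155 counts against 3, a log2 ratio of 5.65 (interval 4.08 to 7.94). EF1Bgamma2 had 76 against 0, at least 24.6-fold higher. The glutaredoxin Potri.008G214800.1 and the ubiquitin extension protein Potri.001G025300.1 each had 61 against 0, at least 19.8-fold higher. Cytochrome P450 Potri.002G025800.1 had 95 against 3 (4.95, interval 3.35 to 7.25) and the lectin receptor kinase 161 against 6 (4.71, interval 3.55 to 6.17). SAUR gene Potri.001G306300.1 had 4.37, the nitrate transporter 3.70 and an ABC transporter (Potri.015G063500.1) 3.47. Metallothionein 3a had 1.04, and ATP synthase CF0 subunit C 1.58.

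Among genes lower in females, cytochrome P450 Potri.014G037900.1 had 5 counts against 628, a log2 ratio of -7.01 (interval -8.64 to -5.78). The Kunitz-type inhibitor Potri.019G124400.2 had 26 against 2014 (-6.32, interval -6.93 to -5.76), and KPI-C1 had 129 against 1033 (-3.04, interval -3.32 to -2.78). The AP2/ERF genes Potri.006G218200.1 and Potri.011G061700.1 had -5.65 and -4.71. A cc-nbs-lrr resistance protein (Potri.005G035700.1) had 0 against 104, at least 35.6-fold lower. The phenylcoumaran benzylic ether reductase-like gene had -4.92, cellulose synthase Potri.002G257900.1 -4.18 and allene oxide synthase -3.14. The chalcone synthases Potri.003G176800.1 and Potri.001G051500.1 had -2.57 and -2.20, and phenylalanine ammonia-lyase, the entry to phenylpropanoids, had 174 counts against 515 (-1.61, interval -1.86 to -1.35). The antenna gene Lhca4 (Potri.015G062200.1) had -2.77, laccase 3 (Potri.010G193100.1) -2.45 and the 2-cys peroxiredoxin -2.23.

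By fixed lists, auxin genes had a median of -1.10 (percentile 0.01) and -0.83 with 0 counts at 3, with 1 higher and 5 lower, and adjusted over the list alone 1 and 6. In their 10 members with at least 100 counts the median was -0.15, inside the central 95%. The secondary wall list had a median of -1.97 (percentile 0.10), with 0 higher and 3 lower by either adjustment. Ethylene-related genes had a median of -0.53 (percentile 2.36), with 2 higher and 16 lower by either adjustment. Without the mismatched reductases the percentile was 2.66, inside the central 95%. Starch and sucrose genes had a median of 0.84 (percentile 97.8), with 1 higher and 0 lower by either adjustment. Defence proteins had 3 higher and 9 lower by either adjustment, with a median of -0.40, inside the central 95%, and -2.23, outside it, in the 9 members with at least 100 counts. Lignin monomer genes had a median of -0.04 and a mean of 0.07, and their median was 0.15 with TMM factors, with 0 calls by either adjustment. Thioredoxin and cell division lists also had medians below 0 and means above 0, without outlying medians. The photosystem and antenna list had 1 higher and 4 lower by either adjustment, or 2 and 2 with TMM factors. Flavonoid genes had 0 and 4 by either adjustment, or 1 and 4 with TMM factors. Phenylpropanoid entry genes had 0 and 2 by either adjustment. Under reduced UV-B these entry genes had 0 and 1, or 0 and 2 adjusted over the list alone. The medians of all 3 lists under ambient UV-B lay inside the central 95%.

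The remaining lists had no median outside the central 95%, or fewer than 5 tested members. Members named only in this paragraph and the next were chosen after their values were seen. Lignin monomer genes were called for caffeoyl-CoA O-methyltransferase alone, lower under ambient UV-B in each sex and lower in females under reduced UV-B, by either adjustment. NAC factors had 0 higher and 2 lower of 28 in males, 1 and 1 in females, 0 and 2 between the sexes under reduced UV-B and 1 and 2 under ambient UV-B, by either adjustment. The last of these became 1 and 0 with TMM factors. WRKY factors had a single call over the 4 comparisons of library pairs, WRKY18, by either adjustment, and with TMM factors a further one, lower in males under ambient UV-B. The jasmonate list was called for allene oxide synthase alone by either adjustment, and 6 of its 9 members were potassium channels taken in by a word pattern. Gibberellin genes had 1 call by either adjustment, higher in females under ambient UV-B. Auxin genes had 1 higher and 2 lower of 37 with UV-B in males, or 0 and 2 with TMM factors, 0 and 1 in females, and 1 and 4 between the sexes under reduced UV-B, by either adjustment. Transport genes had 3 higher and 1 lower with UV-B in males, or 1 and 1 with TMM factors, 2 and 1 in females, and 5 and 7 between the sexes under ambient UV-B, by either adjustment. Among transport members with at least 100 counts the median in males was 0.05, at percentile 2.40. Antioxidant enzymes had 0 and 0 of 6 in males, 0 and 1 in females, 1 and 1 between the sexes under reduced UV-B and 0 and 1 under ambient UV-B, by either adjustment. Cell division genes had 1 and 1 of 35 with UV-B in females, and 2 and 0, then 2 and 2, between the sexes under reduced and ambient UV-B, by either adjustment.

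Small lists were counted without medians. Of 2 COP1-like genes, which act in light signalling, Potri.012G140200.1 was higher in females at both UV-B levels by either adjustment. Neither was called with UV-B. Of 4 heat shock genes a DnaJ gene (Potri.018G034600.1) was lower in females at both levels by either adjustment. The senescence list held pheophorbide A oxygenase (Potri.003G219000.1), which degrades chlorophyll, with 40 counts in females against 10 in males under ambient UV-B, a call by either adjustment. Over all genes tested, the carotenoid, abscisic acid, floral and MYB lists had 0 calls. With TMM factors and with size factors 1 carotenoid gene was called higher in females under ambient UV-B. Adjusted over the list alone, dehydrin of the abscisic acid list was lower in females under ambient UV-B and 1 MADS-box gene was higher in females with UV-B. Of 3 class III peroxidases, 1 was lower in males under ambient UV-B, and 2 adjusted over the list alone. None was called in females, but 1 was lower adjusted over the list alone, and the test between the sexes had 0 calls, or 1 lower adjusted over the list alone. Between the sexes 2 were lower in females under reduced UV-B and 1 under ambient UV-B by either adjustment. Of 2 bHLH genes, bHLH71 was also lower in females at both UV-B levels by either adjustment. Of 2 chlorophyll synthesis genes 1 was higher in females under reduced UV-B by either adjustment. The lists for DNA repair, glutathione S-transferases by that wording, carbon fixation and the circadian clock had 0 tested members.

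Calls between the sexes overlapped across UV-B levels, from 1134 calls under reduced and 1219 under ambient UV-B. At both levels 182 genes were higher in females, against 18.3 for independent lists, and 347 were lower, against 48.8. These expectations are also too low, since 811 and 833 of the calls lay among the 3478 genes with at least 100 counts. With TMM factors these counts were 221 and 308. Only 1 gene and 7 genes were called in opposite directions. The log2 ratios of the sex comparisons had r = 0.69 and rho = 0.62 across 3478 genes, with a covariance of 1.15 against 0.00017 in simulated unchanged libraries.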

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

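The test of sex by UV-B and its threshold were chosen before the data were examined, and the genes given here are those that the named-gene rule picked in any comparison and that this test called. The test called 111 genes with the higher UV-B ratio in females and 217 with the lower, from 1 library per group. TMM factors gave 157 and 126. The test covers counting error only, so its calls alone cannot show that the sexes respond differently. Of the genes named by rule in any comparison, 30 were among those called. Their calls held with TMM factors for 25 and with size factors for 24. All values are log2 ratios of the female UV-B ratio over the male one. Over all tested genes, 9 were called in opposite directions in the sexes, and all 9 were called in this test. That follows almost by construction, because the test uses the same counts, and it adds no separate support.

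Among stress and defence genes, GSTU20 had 8.08, the RNA-dependent RNA polymerase 6.97, the Kunitz-type inhibitor Potri.001G309900.1 4.76, cytochrome P450 Potri.001G270600.1 3.18 and the disease resistance protein Potri.012G074700.1 1.72. EF1Bgamma2 had at least 4.10, a bound against 3 counts. Polyphenol oxidase had -5.65, cytochrome P450 Potri.014G037900.1 -4.92, the Kunitz-type inhibitor Potri.019G124400.2 -3.97, KPI-C1 -1.12, glutathione reductase -1.38 and the 2-cys peroxiredoxin -1.21. The KPI-C1 call ended with both scalings and the peroxiredoxin call with size factors. GSTU20, the RNA-dependent RNA polymerase, polyphenol oxidase and Potri.019G124400.2 are the 4 named genes called in opposite directions in the sexes.

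Among wall and metabolic genes, XTH-6 had 1.89, since it fell further in males, cellulose synthase Potri.002G257900.1 had -3.39 and the aminotransferase -4.52. Among transport genes, the ABC transporter Potri.003G034700.1 had 1.07, the phosphate transporter Potri.005G256100.1 1.74 and the ammonium transporter -1.06, whose call ended with both scalings. Among regulators, NAC factor Potri.019G031400.1 had 2.52, the type-a response regulator -2.01, AP2/ERF factors Potri.001G079800.1 and Potri.005G077300.1 had -2.10 and -1.26, and histone H4 had -1.54. Both AP2/ERF calls ended with both scalings.

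Among plastid-related genes, the Ycf1-like gene had 2.68, ribosomal protein S3 Potri.012G047500.1 2.12, ATP synthase CF0 subunit C 1.14, ribosomal protein S7 1.04 and ribosomal protein L16 (Potri.013G140500.1) 1.01. Lhcb2 had -1.09 and its call ended with both scalings. Ribosomal protein S9, without a plastid-encoded best hit, had -2.57.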

How the results depend on the processing

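The sum of the listed rows as library total, the counts without plastid-encoded best hits and the lists without mismatched members were tried only after the results were seen. Of 88 values of calls and shared calls under an alternative, 56 stayed within 1.5 times the reported count and 32 did not. UV-B in males was 117 higher with TMM factors, 125 with size factors and 117 with the sum of the listed rows, against 264. Sex under ambient UV-B was 599 higher with that sum, against 393, and 256 with at least 100 counts, where fewer genes are tested. The test between the sexes gave 126 lower with TMM factors and 118 with size factors, against 217, and 169 higher and 105 lower with the sum of the listed rows. Genes higher in males and lower in females with UV-B numbered 3 with TMM factors, against 5. With an adjusted p threshold of 0.05, which admits more genes by construction, higher and lower calls were 621 and 402 for UV-B in males, 406 and 410 in females, 1010 and 1281 for sex under reduced UV-B, 868 and 1631 under ambient UV-B, and 326 and 606 between the sexes' responses. An assumed coefficient of variation of 0.1 left 117 and 98 in males and 92 and 99 in females, and 0.3 left 0 and 5 in males, 3 and 11 in females, 28 and 57 for sex under reduced UV-B and 46 and 77 under ambient UV-B. Of the named calls, 0.3 left 1 of 30 in males, 1 of 22 in females, 12 of 44 for sex under reduced UV-B and 17 of 38 under ambient UV-B. In males the move with scaling went with the share of listed tags, 14.9% of the library total under reduced and 17.2% under ambient UV-B. Scaling by the sum of the listed rows, which removes that difference, gave nearly the TMM split. Why the share differed, and the cause of the other moves with scaling, was not tested. No named gene was called in the opposite direction. In males the photosystem and ribosome medians, low at -0.23 and -0.16, changed sign to 0.04 and 0.51, inside the central 95%. That was without mismatched members and those with a plastid-encoded best hit as defined here. The balance of higher and lower calls did turn. UV-B in males became 117 and 232 with TMM factors, 125 and 225 with size factors, and 117 and 230 with the sum of the listed rows. The test between the sexes became 157 and 126 with TMM factors and 161 and 118 with size factors. In females the balance, near even, turned to 161 and 158 with size factors and 190 and 149 with the sum of the listed rows, and sex under ambient UV-B turned to 599 and 576 with that sum. Some list medians inside the central 95% changed sign with the scaling. Without plastid-encoded best hits the calls were 262 and 145 in males, and 157 and 163 in females. With both scalings all 105 list medians stayed on the same side of the central 95%. That is no check of the scaling, because it moves every gene's log2 ratio, and so the matched lists, by the same amount. Of 144 named calls, 136 held with size factors and 137 with TMM factors. With at least 100 counts 43 list medians stayed, 5 moved inside and 7 moved outside, and without mismatched members 11 stayed and 4 moved inside. Depth limits calls to large changes or abundant genes, and a listed 0 can stand for 0 or 1 tag.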

Other observations

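All tests of explanations in this part were chosen only after the results were seen, as were the gene ontology groups and the genes named outside the rule. Kunitz-type inhibitor genes were called with UV-B in each sex. In males Potri.019G124400.2, KPI-C1 and Potri.004G000400.1 (6 to 29 counts) were called higher under ambient UV-B and Potri.019G088200.1 (17 to 0 counts) lower. In females Potri.001G309900.1, KPI-A5 (Potri.010G007900.1, 0 to 20 counts) and KPI-A2.2 (Potri.T029100.1, 0 to 35 counts) were called higher and Potri.019G124400.2 lower. With TMM factors only Potri.019G124400.2 stayed higher in males. No Kunitz-type gene was called in the same direction in both sexes, and the test between the sexes called 3, Potri.019G124400.2, KPI-C1 and Potri.001G309900.1. The KPI-C1 call ended with both scalings, and the other 4 genes had no call in that test. Calls between the sexes in these libraries thus cover 2 genes and not the family. No spread between pools was tried for that test, and the UV-B calls of these 2 genes ended with an assumed coefficient of variation of 0.3.

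A few gene ontology groups stood out between the sexes at both UV-B levels, and most did so at one level only. Of 196 terms, 7 lay in the lowest 0.5% of matched sets and 3 in the highest 0.5% under reduced UV-B, and 4 and 7 under ambient UV-B, where 0.98 would be expected in each tail. Genes of cell recognition had low values in females, with medians of -0.79 under reduced UV-B and -0.88 under ambient UV-B, at percentiles 0.04 and 0.05 of matched sets. Carbohydrate binding was low as well, at percentiles 0.08 and 0.02. Its calls were 3 higher and 15 lower under reduced UV-B and 4 higher and 18 lower under ambient UV-B. Antioxidant activity was low at both levels, at percentiles 0.37 and 0.03, whereas the fixed list of 6 antioxidant enzymes was inside the central 95% at both, with medians of 0.48 and -0.33. Plastid stroma had medians of 0.36 and 0.08 at percentiles 99.98 and 99.8, but its calls were 22 higher and 8 lower under reduced UV-B and 15 higher and 18 lower under ambient UV-B. Genes whose identifiers begin with Potri.019G were called at both UV-B levels in 19 of 284 cases, 6.69%, inside the range of 2.75% to 8.72% over the numbered identifier groups. For UV-B itself, 9 terms lay in the lowest and 2 in the highest 0.5% in males, and 8 and 0 in females. External encapsulating structure organization was low in both sexes, at percentiles 0.03 and 0.395. Its calls were 0 higher and 1 lower in males, and 2 higher and 4 lower in females.

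The first pattern weighed is that sex separated the libraries more than UV-B did. Scaling is argued against as the whole cause, since with TMM factors the smaller sex comparison still had 3.23 times the calls of the larger UV-B comparison, 1129 against 349. Sequence differences at the tag site between male and female plants could remove a tag in one sex. Of the 529 genes called in the same direction at both UV-B levels, 18.0% had at most 3 counts in both libraries of one sex, against 2.94% at one UV-B level for the 34 genes called for UV-B in the same direction in both sexes. Transcription limited to one sex gives the same picture, so these cannot be told apart without the tags, and the genotype of the cuttings and sex itself stay open, untested.

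The second pattern is the low place of the cell wall lists under ambient UV-B in both sexes. Low counts are argued against for the primary wall list, since among its 7 members with at least 100 counts the median was at percentile 0.12 or lower in each sex. The secondary wall list had too few such members for a median, so low counts stay open for it. Less vascular tissue in the sampled leaves is a candidate explanation that stays open. The secondary wall list without the 3 members it shares with the primary wall list, 8 genes, was at percentile 1.53 in males and 0.57 in females, and its most abundant members, laccase 3 and a fasciclin gene (Potri.015G129400.1), had 35 and 53 and 28 and 23 counts in males. A direct lowering of wall synthesis by UV-B is equally open, untested.

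The third pattern is the fall of genes with a plastid-encoded best hit in males under ambient UV-B, a single library, while in females their median was also low, at -0.19, without a call. An equal loss of all plastid transcripts is argued against, for 12 such genes with at least 500 counts in males under reduced UV-B. Of these, 6, that is 50%, had a log2 interval wholly above -0.5, while 4 were called lower. That bound cannot decide against a general fall with differences between genes. All 12 log2 ratios lay below 0.322, the male median of genes with at least 100 counts, and the highest was 0.320. A single change per plastid gene is argued against too, but only for the best hits RNA polymerase beta'' subunit and Ycf1-like. In all, 7 of 10 pairs of genes with the same best hit had intervals apart. All of these came from those hits, with genes shared between pairs, and the intervals cover counting error only. The pair for NADH dehydrogenase subunit 6 overlapped. Tags shared between the plastid genome and its nuclear copies could give such a mixture, and for the 41 genes this cannot be told apart from separate transcript changes, because the tags themselves are not analysed here.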
